A study of Homo sapiens with 10 samples.

How the data were processed

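RNA was measured by sequencing in 10 libraries from 3 human lung cancer cell lines that carry different p53 mutations: V157F in NCI-H2087, R158L in NCI-H441 and R158P in NCI-H2110. Per the labels, the cells had been transfected with a control siRNA or with an siRNA against p53, RNA was purified with an RNeasy Plus kit, and libraries were made with a Lexogen mRNA kit. The sample titles speak of a knockout, whereas the protocol and the experiment field name an siRNA, so the treatment is described here as a knockdown. NCI-H2087 and NCI-H441 had 2 libraries per arm and NCI-H2110 had 1 per arm, numbered replicate 2. Each mutation occurs in 1 line, so line and mutation are not separable in these data. The labels do not state whether replicates were separate cultures, and the p-values measure only the spread between these samples.

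The deposited file is a table of whole-number counts per gene, with 57736 Ensembl gene IDs and no normalization. The submitters' processing notes list Bowtie2, RSEM 1.2.12 and the hg19 build, without giving the role or order of the tools. Whether the counts are rounded RSEM expected counts is not stated. A reference names table gave symbols for 51959 IDs, GENCODE 29 gave 342 more, and 5435 stayed unnamed. All 10 libraries were 0 for 28408 IDs. Library totals ran from 18336672 to 25810934 counts. The table holds no genes of the mitochondrial genome, so those were not analysed here. GENCODE 29 served for names, gene types and transcript sequences, and its exon and coding positions defined the 3′ UTRs. Coordinates were used for nothing else.

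Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr on the 6 groups of line and siRNA, which left 17978 genes with 99.96% of the counts, and library sizes were scaled by TMM. For NCI-H2087, for NCI-H441 and for the difference between their changes, a quasi-likelihood model with 1 mean per group was fitted to all 10 libraries (4 residual degrees of freedom). The change common to the 3 lines was tested with an additive model of line and siRNA (6 residual degrees of freedom). All tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and genes with adjusted p below 0.05 were called. Fold changes are log2 values of p53 siRNA over control siRNA, with standard errors derived from the F statistic, and levels are CPM on TMM library sizes. The common biological coefficient of variation was 19.8%. NCI-H2110 has no replicate, and its 2 libraries were compared as log2 ratios of CPM with a prior count of 2 among genes of at least 50 counts in either library, without a test.

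The replicate numbers were checked as a pairing. Across 9330 genes with a mean log2 CPM of at least 3, the difference between replicates 1 and 2 in the control arm correlated with that in the p53 siRNA arm, with r = 0.534 in NCI-H2087 and r = 0.595 in NCI-H441. Libraries of the same number in a line were therefore also fitted as a replicate block (2 residual degrees of freedom, 4 in the additive model), and blocked values stand beside the gene counts and gene lists that they move by over 1.5 times or whose call they change. For the difference between lines, only some of the lists moved are given. Replicates were not copies of each other, with a chi-square per gene of 21.3 to 63.6.

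The gene lists, 24 in number, were tested with camera at a preset correlation of 0.01 on log2 CPM, adjusted over the 24 lists within each contrast, then again with the correlation estimated per list, and with fry. Of the 566 list entries, 9 found no gene in the table. The lists cover p53-activated targets, genes reported to depend on mutant p53, mitosis, replication, cholesterol, fatty acid and nucleotide synthesis, the proteasome, ribosomal proteins, histones, interferon, NF-kB, hypoxia, ATF4, unfolded-protein and NRF2 responses, epithelial and mesenchymal genes, and markers of alveolar type 2, club and goblet, basal and squamous, neuroendocrine, fibroblast, and immune or endothelial cells. For NCI-H2110 the median log2 ratio of each list with at least 5 measured members was ranked among 10000 random lists matched on expression. Shared calls of NCI-H2087 and NCI-H441 were tested with Fisher's exact test, one-sided.

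Genes were named by a fixed rule, of which 1 gene is not reported here: up to 10 rises and 10 falls of largest size per contrast among called genes with a mean CPM of at least 5 and every p53 siRNA library on the same side of every control library of its line; then up to 4 members of a list with the smallest p. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were named, as for the difference between lines. The 8 largest rises and falls were taken in NCI-H2110. The groups, tests of genes and lists, the lists, naming rule and alternative settings were chosen before the data were examined, except where stated. The search for short sequences and the splits of the libraries were not part of that plan.

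Matches to short sequences were searched in the 3′ UTRs of 10381 genes with a UTR of at least 50 bases and a mean CPM of at least 5. Each 7-base sequence found in at least 100 genes was scored by the mean fold change of genes with it less that of genes without it, within 20 bins of UTR length, with 10000 permutations within bins. The strongest rise among all 15704 sequences and the strongest fall among the 2950 that a p53 siRNA could match were chosen in NCI-H2087 and tested in NCI-H441. The scores were repeated after regression on base and dinucleotide shares and length of the UTR.

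Alternatives were DESeq2 1.42.0 or limma-voom in place of edgeR, RLE factors or library totals in place of TMM, other filters, the replicate block, fits of a line alone, and leaving out each library in turn, which leaves an arm with 1 library that is assumed to vary like the other groups. On simulated data with 200 changed genes per fit, the single-line test called 4% of 1.5-fold, 42.8% of 2-fold and 97% of 4-fold changes and 0.05% of unchanged genes. In the additive model these were 39.8%, 92%, 100% and 0.08%, and for the difference between lines 0.5%, 5.5%, 78.8% and 0.03%. On simulated data camera called 5 of 5 lists shifted by 0.5 log2 and 0 of 115 others. Those lists were random genes simulated independently. The result does not carry over to lists with correlated members, such as hypoxia genes (estimated correlation 0.605 in the fit for NCI-H2087). A planted rise of 0.1 log2 at 1 sequence was ranked highest in 20 of 20 simulations. The planted sequences were drawn from those found in many genes, and fold changes of NCI-H2087 were shuffled within length bins. Shuffling removes trends with base composition, so the result does not carry over to lines with such a trend. Sequence work and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.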

Results

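Counts per gene were collected from 10 libraries of 3 lung cancer cell lines with different p53 mutations, each transfected with a control siRNA or an siRNA against p53. NCI-H2087 carries V157F, NCI-H441 carries R158L and NCI-H2110 carries R158P. NCI-H2087 and NCI-H441 had n = 2 libraries per arm, and NCI-H2110 had 1 library per arm and therefore no replicate. The control libraries held 18336672 and 25178500 counts in NCI-H2087, 23073288 and 25810934 in NCI-H441 and 25638101 in NCI-H2110. The p53 siRNA libraries held 25115074 and 25270810, 24904295 and 24214760, and 23353257 counts in the same order of lines. The comparisons asked which transcripts changed with p53 siRNA. Levels are CPM with the SD of the replicates, and changes are log2 fold changes ± SE from edgeR.

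TP63, a p53 paralog and basal cell regulator, fell in NCI-H2087 by 2.44 ± 0.30 log2 (adjusted p = 0.00248), from 7.22 and 13.3 CPM to 2.09 and 1.69 CPM. It stood at 22.3 and 24.4 CPM against 18.6 and 17.4 CPM in NCI-H441, and at 45.2 against 58.4 CPM in NCI-H2110.

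**Figure D1:**
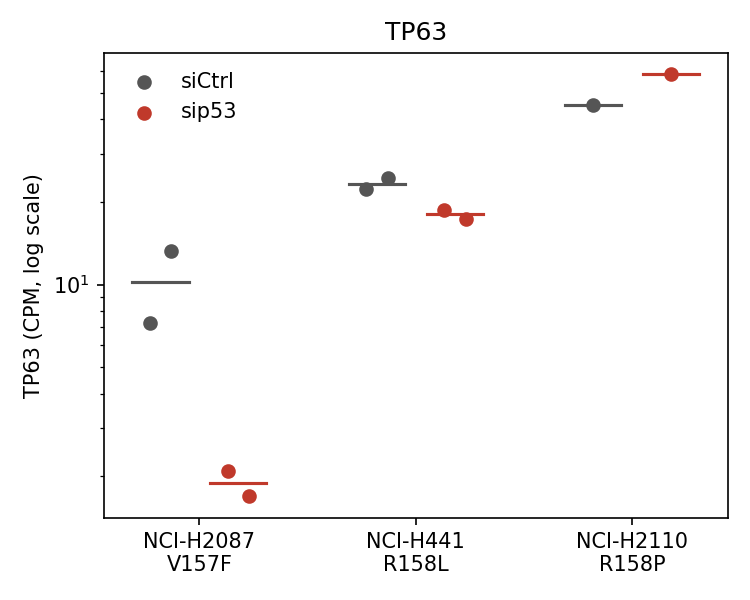
TP63 levels in each library (CPM, log scale) by cell line, with control siRNA in grey and p53 siRNA in red; points are libraries and bars are group means. TP63 was 7.22 and 13.3 CPM in the NCI-H2087 controls and 2.09 and 1.69 CPM with p53 siRNA.

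In NCI-H2087, MMP1, an interstitial collagenase, rose from 15.8 ± 1.74 to 200.4 ± 56.5 CPM (3.67 ± 0.47), and ITGA2, a collagen-binding integrin subunit, rose from 153 ± 18.4 to 1416 ± 265 CPM (3.21 ± 0.33). Other large rises were in VGF, a secreted neuropeptide precursor (3.75 ± 0.79), DHRS9, a short-chain dehydrogenase (3.72 ± 0.31), SPOCD1 (3.44 ± 0.32) and TMCC3 (3.28 ± 0.40). KRT4, a keratin of stratified epithelium, fell from 588 ± 78.0 to 45.1 ± 32.1 CPM (−3.71 ± 0.44), and the surfactant protein gene SFTPA1 fell from 612 ± 40.4 to 69.3 ± 64.3 CPM (−3.14 ± 0.74). The surfactant protein gene SFTPB (−4.05 ± 0.41) and the collagenase gene MMP13 (−3.23 ± 0.24) fell too. Falls of similar size were in C16orf89 (−3.70 ± 0.32), ENPP2, which encodes the lysophospholipase autotaxin (−3.53 ± 0.39), the metalloreductase STEAP4 (−3.33 ± 0.44), the receptor tyrosine kinase ERBB4 (−3.26 ± 0.66), the interferon-induced OAS2 (−3.15 ± 0.34) and the receptor TNFRSF19 (−3.05 ± 0.50). The gene ENSG00000132130, which has no symbol here, rose by 4.32 ± 0.37 log2. The noncoding RNAs LINC00707 (3.24 ± 0.55) and LINC00880 (3.17 ± 0.35) also rose. POLR2J2, an RNA polymerase subunit gene with near-identical copies, rose by 3.73 ± 0.31 log2, while in NCI-H2110 its counts were 421 and 98.

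In total 1560 of 17978 genes were called in NCI-H2087 by edgeR, 896 higher and 664 lower, of which 1046 differed at least 2-fold. The adjusted p of the named genes ran from 0.000375 for MMP13 to 0.031 for SFTPA1. With the replicate block 4570 genes were called, among them all 1560. Without control replicate 1 the count was 358, without control replicate 2 it was 177 and without p53 siRNA replicate 2 it was 641, and among the genes named by size the calls of VGF, LINC00707, ERBB4, SFTPA1, MMP1 and TNFRSF19 were lost without at least 1 library (highest adjusted p = 0.138). Scaling by library totals alone moved the median of all genes from −0.04 to −0.21 log2, and the higher genes from 57.4% to 33.2% of those called. Of the genes that rose, MMP1, ITGA2, CDKN1A and CYP51A1 carry the sequence GAATATA in the 3′ UTR, as do MMP13, IFIT1 and CXCL1, which fell. Of those that fell, SFTPB, SFTPA1, SFTPA2, STEAP4 and TP63 carry CACCCTT, as do TNFAIP3 and LIF, which rose.

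**Figure D2:**
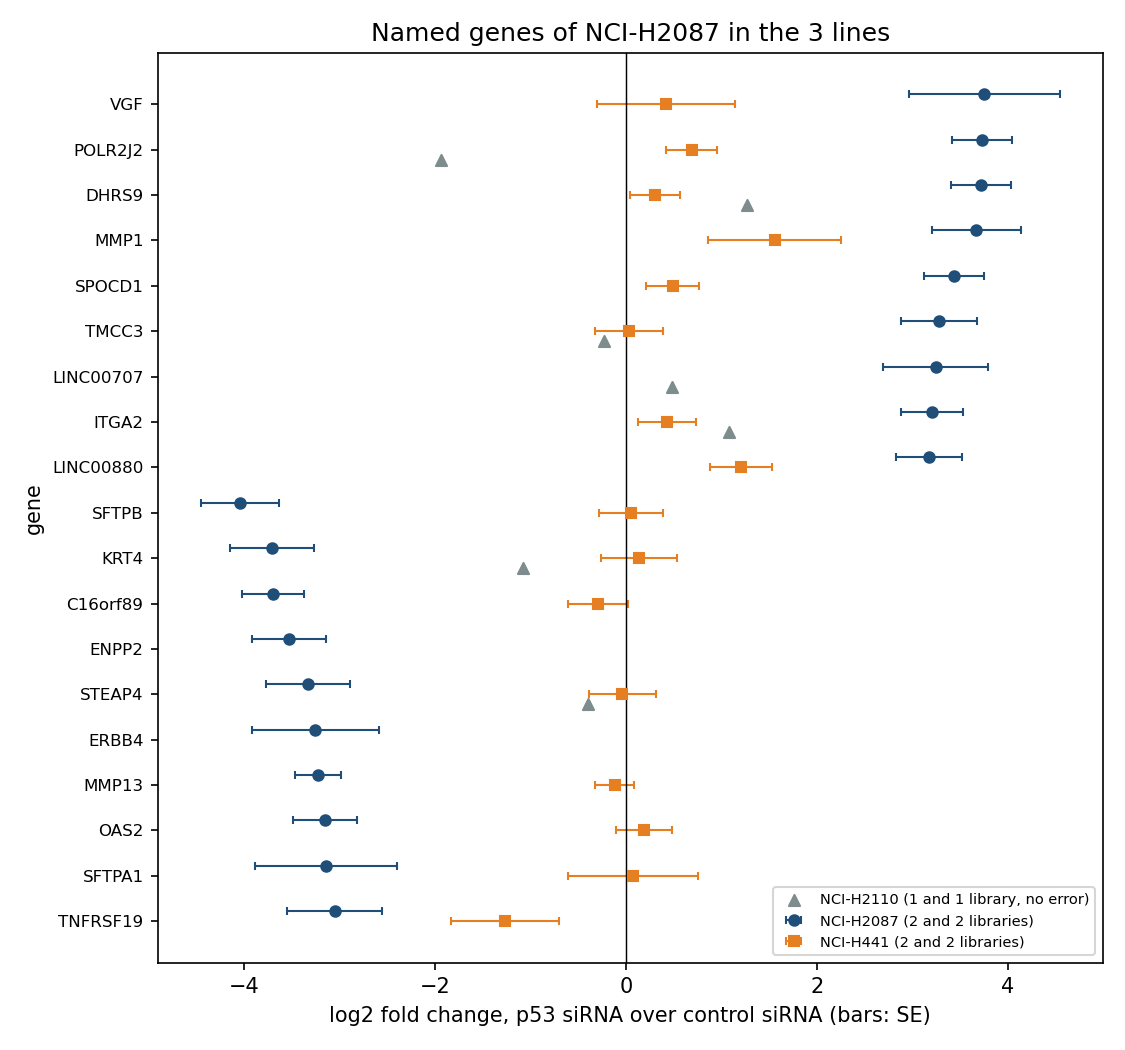
Log2 fold changes of the genes with a symbol named by size in NCI-H2087 (p53 siRNA over control siRNA), with SE bars for NCI-H2087 and NCI-H441; triangles are NCI-H2110 log2 ratios of 1 library per arm. Values with under 10 counts in an arm of a replicated line are not drawn, and SFTPB was −4.05 in NCI-H2087 and 0.05 in NCI-H441.

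Interferon-stimulated genes were lower in NCI-H2087: of 32 members 14 fell, 1 rose and the others were not called, with a median of −0.81 log2. IFIT2 (−2.23 ± 0.23), MX1 (−2.32 ± 0.34) and IFIT1 (−1.66 ± 0.24) fell. Camera gave adjusted p = 1.36e-07, and adjusted p = 0.723 with an estimated correlation; 19 fell and 1 rose adjusted over the list alone. Of 13 alveolar type 2 markers 4 fell and 0 rose, with a median of −1.68 log2: SFTPB, SFTPA1, SFTPA2 (−3.03 ± 0.70) and LAMP3, a lysosomal protein of lamellar bodies (−1.68 ± 0.39). The list had camera adjusted p = 0.00262, and adjusted p = 0.723 with an estimated correlation; 8 fell and 1 rose adjusted over the list alone. The replicate block gave 22 interferon genes that fell and 1 that rose, and 10 alveolar markers that fell and 1 that rose.

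Ribosomal protein genes had positive changes in 41 of 41 cases, and in 40 of 41 under scaling by library totals, with a median of 0.46 log2. Only RPS4X was called (0.62 ± 0.16), against 24 rises and 0 falls adjusted over the list alone; camera gave adjusted p = 5.44e-11, and adjusted p = 0.723 with an estimated correlation. Proteasome genes rose in 4 of 31 cases and fell in 0, among them the subunits PSMD2 (1.11 ± 0.18) and PSMD14 (0.99 ± 0.20), with a median of 0.35 log2. Their camera adjusted p = 2.54e-05, or adjusted p = 0.75 with an estimated correlation, and 4 rose adjusted over the list alone. Hypoxia and glycolysis genes rose in 5 of 26 cases and fell in 0, with a median of 0.61 log2: NDRG1, a hypoxia-induced gene (1.38 ± 0.23), hexokinase HK1 (0.94 ± 0.18), the growth factor VEGFA (0.87 ± 0.18) and PFKP, a phosphofructokinase (0.71 ± 0.16) were among them. Camera gave adjusted p = 0.00135, and adjusted p = 0.869 with an estimated correlation; 6 rose adjusted over the list alone. The list's call was lost without p53 siRNA replicate 1 (adjusted p = 0.468) or control replicate 2 (0.0737). Nucleotide synthesis genes had a median of 0.27 log2 over 27 members, with camera adjusted p = 0.00538, or adjusted p = 0.723 with an estimated correlation. That call was lost without control replicate 2 (0.246) or p53 siRNA replicate 1 (0.107). Scaling by library totals gave medians of 0.10 for nucleotide synthesis (18 of 27 positive, against 26), 0.17 for proteasome and 0.28 for ribosomal protein genes. Under the replicate block 31 ribosomal protein, 11 proteasome, 13 hypoxia and 5 nucleotide synthesis genes rose and 0 fell. In the same libraries the share of counts on nuclear pseudogenes of mitochondrial genes was 4.41% and 5.02% with control siRNA, and 2.25% and 2.06% with p53 siRNA.

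Among 38 genes that wild-type p53 activates, 3 rose and 1 fell in NCI-H2087, and 3 rose and 1 fell adjusted over the list alone. The cell cycle inhibitor CDKN1A rose by 2.17 ± 0.18 log2, the stress gene GADD45A by 1.34 ± 0.18 and the kinase gene PLK3 by 2.11 ± 0.29. The list's median was 0.06 and its mean −0.06 log2, with camera adjusted p = 0.843, and its median was −0.11 under scaling by library totals. Of 23 genes reported to depend on mutant p53, the receptor kinase AXL rose (2.29 ± 0.23) and the chemokine CXCL1 fell (−2.34 ± 0.33), with camera adjusted p = 0.369; 4 rose and 2 fell adjusted over the list alone. In the blocked fit 7 rose and 5 fell among the p53-activated genes, and 6 rose and 4 fell among those reported to depend on mutant p53.

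Epithelial genes went both ways in NCI-H2087, with 5 of 22 rising and 3 falling (7 and 5 adjusted over the list alone; camera adjusted p = 0.503; median −0.01, or −0.19 under scaling by library totals, and mean 0.18 log2). The keratins KRT19 (2.38 ± 0.21), KRT7 (1.88 ± 0.25), KRT8 (1.26 ± 0.16) and KRT18 (1.18 ± 0.16) rose. Of 22 mesenchymal genes 6 rose and 1 fell, or 8 and 3 adjusted over the list alone, with camera adjusted p = 0.119. AXL, the matrix protein TNC (1.58 ± 0.20) and the transcription factor SNAI2 (1.57 ± 0.25) rose, and FBN1, a microfibril protein, fell by 2.10 ± 0.23 log2. Basal and squamous markers rose in 2 of 10 cases and fell in 2 (3 and 2 adjusted over the list alone; camera adjusted p = 0.844): the integrin ITGB4 (0.97 ± 0.16) and SERPINB5 (0.86 ± 0.20) rose, and TP63 and SOX2, a stem cell transcription factor (−1.77 ± 0.35), fell. NF-kB genes rose in 2 of 24 cases and fell in 4 (2 and 5 adjusted over the list alone; camera adjusted p = 0.696), with TNFAIP3, a feedback inhibitor, up by 2.19 ± 0.34 log2, the cytokine LIF up by 1.07 ± 0.20, and CXCL1 and the adhesion molecule ICAM1 (−1.07 ± 0.19) down. In the blocked fit 7 epithelial genes rose and 7 fell, 9 mesenchymal genes rose and 3 fell, and 4 NF-kB genes rose and 7 fell. Of 43 called list members that the naming rule gave in this line beyond those named by size, 11 kept their call when each library was left out in turn: AXL, CDKN1A, CXCL1, FBN1, IFIT1, IFIT2, KRT19, KRT7, MX1, TNC and TP63.

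The remaining lists showed few calls in NCI-H2087. Of 24 NRF2 targets the iron storage gene FTL rose (1.17 ± 0.24) and the glutathione synthesis gene GCLC fell (−1.09 ± 0.17; camera adjusted p = 0.763), and 3 rose and 3 fell adjusted over the list alone. Of 25 ATF4 targets DDIT4 rose (2.26 ± 0.59; camera adjusted p = 0.14), of 13 fatty acid synthesis genes the elongases ELOVL6 (1.39 ± 0.22) and ELOVL1 (0.89 ± 0.18) rose (camera adjusted p = 0.418), and of 25 cholesterol synthesis genes CYP51A1 rose (0.76 ± 0.19; camera adjusted p = 0.338). Adjusted over the list alone, these lists gave 0, 2 and 0 calls in the same order. The goblet cell factor SPDEF rose (2.33 ± 0.33) among 7 club and goblet markers, whose SCGB3A2 had 19 and 19 counts against 1 and 1 (camera adjusted p = 0.696; 1 rise and 3 falls adjusted over the list alone). Of 5 immune or endothelial markers CD68, a lysosomal protein of macrophages, rose (1.33 ± 0.31; camera adjusted p = 0.994; 1 rise and 2 falls adjusted over the list alone). The 7 lists of mitosis, replication, nucleotide synthesis, unfolded-protein response, histones, neuroendocrine and fibroblast genes had 0 of 139 members called by edgeR, with 17 at an unadjusted p below 0.05, 10 called by DESeq2 and 1 by limma-voom. Camera gave adjusted p = 0.89 for replication, 0.696 for the unfolded-protein response, 0.696 for histones, 0.844 for neuroendocrine and 0.89 for fibroblast genes. For the 35 mitosis genes camera gave adjusted p = 0.122, and adjusted p = 0.927 with an estimated correlation; with the replicate block 8 were higher and 1 lower, and the preset correlation gave 0.00314. Their median was 0.22 log2 with 33 positive members, and 0.04 with 21 under scaling by library totals. The block also gave 6 rises and 6 falls for NRF2 targets, 4 and 1 for ATF4 targets, 3 and 1 for fatty acid synthesis, 2 and 6 for cholesterol synthesis, 4 and 1 for the unfolded-protein response, 3 and 4 for replication, 0 and 2 for histones, 1 and 2 for club and goblet markers and 1 and 1 for immune or endothelial markers.

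In NCI-H441, which carries R158L p53, p53 siRNA left 1 called gene. The 5 rises with the smallest p did not pass: EFHD2, an actin-binding protein (1.29 ± 0.18, adjusted p = 0.325), EHD2, a membrane-remodelling ATPase (1.03 ± 0.16, 0.325), the epithelial cadherin CDH1 (1.37 ± 0.23, 0.325), TULP3 (0.90 ± 0.16, 0.373) and the annexin ANXA2 (1.13 ± 0.20, 0.373). CDH1 was at 492 ± 11.8 CPM with control siRNA and 1270 ± 206 CPM with p53 siRNA, and ANXA2 at 853 ± 106 and 1869 ± 372 CPM. The corresponding falls did not pass either, each with adjusted p = 0.325: EFCAB14 (−1.07 ± 0.17), CCDC43 (−1.19 ± 0.19), CMTM6, a stabiliser of PD-L1 (−1.38 ± 0.22), the pseudogene PSMC1P1 (−1.44 ± 0.24) and the cation channel TRPV1, with 39 and 54 counts against 3 and 0. By edgeR 796 genes had an unadjusted p below 0.05, against 899 expected by chance; DESeq2 called 25 genes, limma-voom 1 and the fit of this line alone 0. With the replicate block 75 genes were called, 49 higher and 26 lower, and all 10 of the genes just named passed, with adjusted p from 0.00102 for EFHD2 and ANXA2 to 0.00966 for TULP3.

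No list member was called in NCI-H441 without the replicate block: over the 24 lists, 0 of 520 members passed by edgeR, 32 had an unadjusted p below 0.05, DESeq2 called 2 and limma-voom 0. The replicate block called 2 epithelial genes and 1 each of the mesenchymal, NF-kB, basal and nucleotide synthesis lists, all higher. As groups, 4 lists had camera adjusted p below 0.05 without the replicate block, each with a positive median, and 8 had it with the block. Epithelial genes had a median of 0.21 log2 (adjusted p = 0.00878; adjusted p = 0.631 with an estimated correlation), with CDH1 called adjusted over the list alone. Mesenchymal genes had a median of 0.35 (adjusted p = 0.0225; adjusted p = 0.631 with an estimated correlation), and basal and squamous markers 0.53 (the same values of adjusted p), with KRT6A at 1.75 ± 0.34 and ITGB4 at 0.54 ± 0.16 called adjusted over the list alone. Ribosomal protein genes had a median of 0.16 (adjusted p = 0.00172; adjusted p = 0.829 with an estimated correlation). Leaving out single NCI-H441 libraries ended all 4 calls: epithelial without control replicate 2 (0.287) or p53 siRNA replicate 1 (0.181), and ribosomal without p53 siRNA replicate 1 (0.447) or control replicate 2 (0.156). The mesenchymal list was lost without control replicate 1 (0.123), p53 siRNA replicate 1 (0.0578) or p53 siRNA replicate 2 (0.182), and the basal list without the same libraries (0.164, 0.0578 and 0.133). The 4 lists added by the block were mitosis (median −0.17, 0.00136) and proteasome genes (−0.13, 0.0453), both lower, and NF-kB (0.21, 0.0123) and hypoxia genes (0.20, 0.0281), both higher; without the block these had adjusted p = 0.867 with an estimated correlation for mitosis and 0.829 for the others. Without the block the other 20 lists had adjusted p from 0.0582 to 0.883; the interferon list had a median of 0.04 and a mean of −0.09 log2, and its median was −0.01 under scaling by library totals. The p53-activated targets had a median of −0.10 log2 and camera adjusted p = 0.191.

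**Figure D3:**
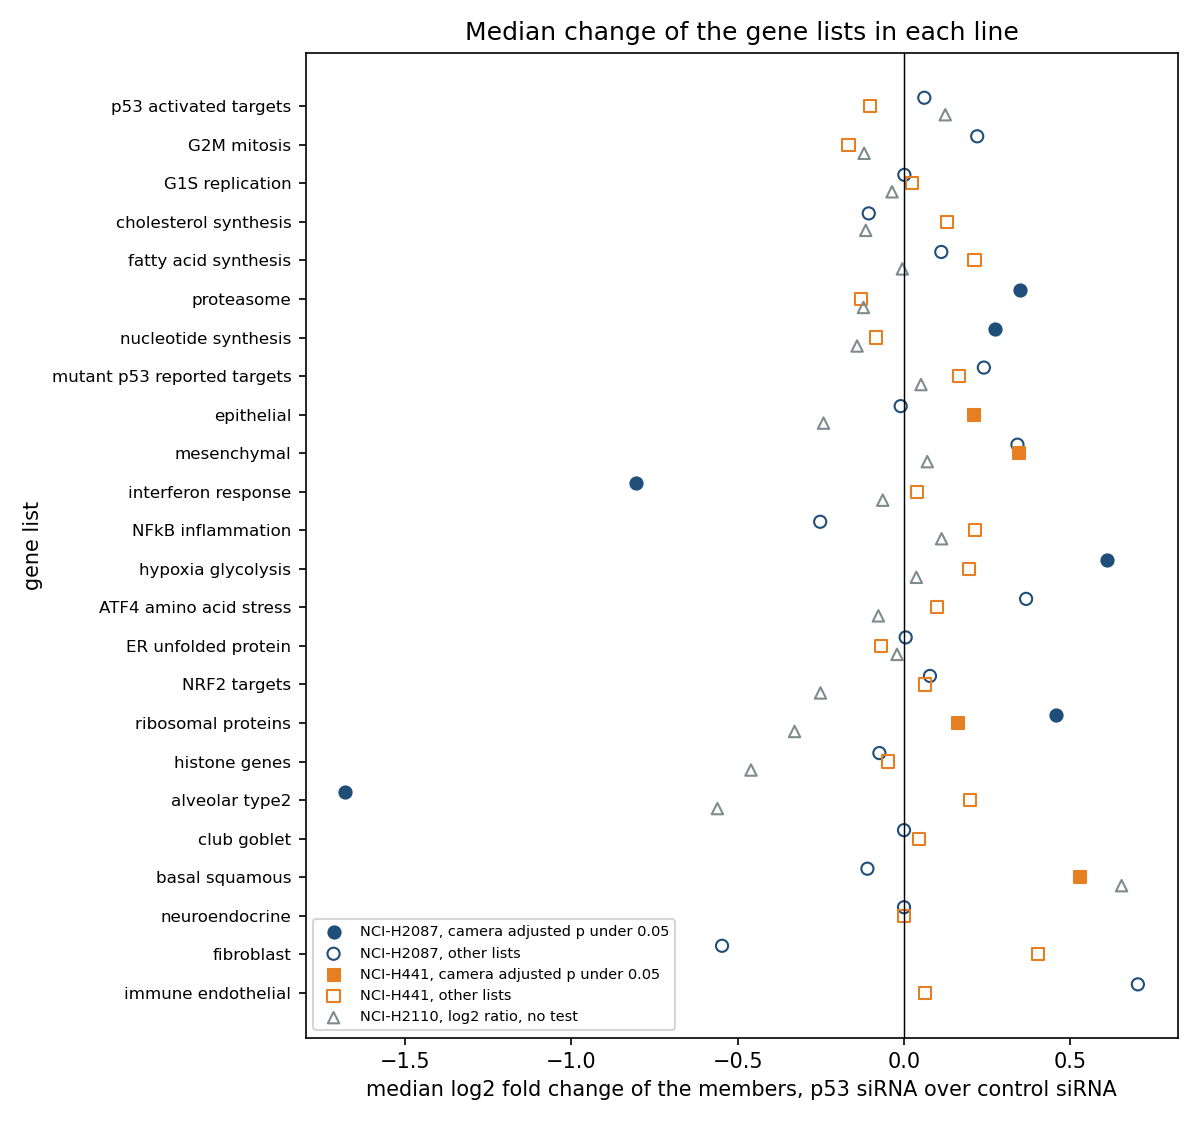
Median log2 fold change of 24 gene lists in NCI-H2087 and NCI-H441, and of the 20 with at least 5 measured members in NCI-H2110 (p53 siRNA over control siRNA), with filled symbols for camera adjusted p below 0.05; all of these calls were lost with an estimated correlation. Alveolar type 2 markers had a median of −1.68 in NCI-H2087, 0.20 in NCI-H441 and −0.56 in NCI-H2110.

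Across the 3 lines, p53 siRNA changed 71 genes in an additive model, 61 up and 10 down. Their group means moved in the fitted direction for 71 genes in NCI-H2087, 68 in NCI-H441 and 62 in NCI-H2110. CARNMT1, a carnosine methyltransferase, rose by 1.81 ± 0.26 log2, from 7.98 ± 0.06 to 51.0 ± 0.35 CPM in NCI-H2087, from 18.3 ± 0.69 to 37.6 ± 11.9 CPM in NCI-H441 and from 18.0 to 58.1 CPM in NCI-H2110. EFHD2 (1.72 ± 0.28), the pregnancy glycoprotein PSG1 (1.61 ± 0.30), the interleukin 15 receptor chain IL15RA (1.60 ± 0.25), the focal adhesion protein TNS4 (1.55 ± 0.26), the claudin CLDN12 (1.44 ± 0.27), LCLAT1, a cardiolipin acyltransferase (1.42 ± 0.21), ANXA2 (1.35 ± 0.17), the mitochondrial transporter ABCB10 (1.29 ± 0.22) and the magnesium transporter NIPA1 (1.19 ± 0.15) also rose. CMTM6 fell by 1.48 ± 0.16 log2, from 71.4 ± 2.51 to 20.3 ± 4.49 CPM, 97.9 ± 21.8 to 37.6 ± 4.07 CPM and 51.1 to 25.1 CPM in the same order of lines. CCDC43 (−1.27 ± 0.17), EFCAB14 (−1.17 ± 0.14), the ganglioside synthase ST3GAL5 (−1.13 ± 0.18), KLHL5 (−0.71 ± 0.13), C18orf32 (−0.71 ± 0.13) and the splicing factor LUC7L2 (−0.70 ± 0.13) fell as well.

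Of 17978 genes tested by edgeR, those named had adjusted p from 0.00574 (CMTM6) to 0.0458 (CLDN12). With the replicate block 71 genes were called, 58 of them shared, and CLDN12 (adjusted p = 0.0605), LUC7L2 (0.0605) and C18orf32 (0.0574) were not. The count rests on the NCI-H2087 libraries and on others: it was 2 without NCI-H2087 control replicate 1, 7 without control replicate 2, 8 without p53 siRNA replicate 1 and 20 without p53 siRNA replicate 2, 23 without NCI-H441 control replicate 1 and 117 without NCI-H441 p53 siRNA replicate 2. Of the genes just named, CMTM6 kept its call without each library, and the others had a highest adjusted p from 0.0676 to 0.214. Of the called genes with a searched 3′ UTR, 30 of 52 higher genes carried the sequence GAATATA, among them EFHD2, IL15RA, ABCB10, NIPA1 and CDH1, against 16.1% of other genes; 4 of 8 lower genes carried CACCCTT, namely CCDC43, EFCAB14, LUC7L2 and ST3GAL5, against 12.1%. TNS4, CLDN12 and TULP3 also carry CACCCTT and were called higher. Both sequences were chosen in NCI-H2087, whose libraries also carry these calls, so the shares partly restate that choice.

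Among 22 mesenchymal genes LOXL2, a lysyl oxidase (1.14 ± 0.21), and SNAI2 (1.12 ± 0.21) rose across the lines and 0 fell (4 and 0 adjusted over the list alone; 1 and 0 with the replicate block). In NCI-H2110 6 of 12 measured members were positive, with a median of 0.07 log2. Their median was 0.20 log2, with camera adjusted p = 0.0132, or adjusted p = 0.361 with an estimated correlation, and fry adjusted p = 0.0196. CDH1 rose by 1.14 ± 0.15 log2 among 22 epithelial genes (5 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.402), and ITGB4 by 0.73 ± 0.12 among 10 basal and squamous markers (6 and 2 adjusted over the list alone). The calls of LOXL2, SNAI2, CDH1 and ITGB4 were each lost without at least 1 library. The basal list had a median of 0.57 log2 and camera adjusted p = 0.0423, or adjusted p = 0.763 with an estimated correlation. Interferon genes had a median of −0.36 (camera adjusted p = 4.1e-05; adjusted p = 0.763 with an estimated correlation), alveolar type 2 markers −0.40 (0.0423; adjusted p = 0.911 with an estimated correlation), hypoxia genes 0.30 (0.000489; adjusted p = 0.911 with an estimated correlation) and ribosomal protein genes 0.18 (7.69e-05; adjusted p = 0.911 with an estimated correlation). The 21 lists other than mesenchymal, epithelial and basal had 0 of 466 members called by edgeR, 71 at an unadjusted p below 0.05, 17 called by DESeq2 and 2 by limma-voom; the replicate block called 1 hypoxia gene. In single lines the ribosomal median was 0.46 in NCI-H2087, 0.16 in NCI-H441 and −0.33 in NCI-H2110, where 1 of 41 was positive, and the interferon median was −0.81, 0.04 and −0.06. The basal median was −0.11, 0.53 and 0.65, and the alveolar median −1.68, 0.20 and −0.56. Scaling by library totals moved the ribosomal median across the lines to 0.09 and the mesenchymal median to 0.10. The interferon and ribosomal calls held without each library; the mesenchymal call was lost without NCI-H441 p53 siRNA replicate 2 (0.0589) and the hypoxia call without NCI-H2087 p53 siRNA replicate 1 (0.0677). The alveolar call was lost without any of 7 libraries (up to 0.192, without NCI-H2087 control replicate 2) and under scaling by library totals (0.121), and the basal call without any of 6 (up to 0.171, without NCI-H2110 p53 siRNA) and with the replicate block (0.0536). The genes reported to depend on mutant p53 had a median of 0.12 log2 (0.03 under scaling by library totals), camera adjusted p = 0.162 and fry adjusted p = 0.0196.

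The change differed between NCI-H2087 and NCI-H441 for 74 genes, 43 with the more positive change in NCI-H2087 and 31 with the more negative; under scaling by library totals these were 40 and 46. PHLDA1, a gene induced by growth factor signalling, changed by 2.67 in NCI-H2087 against −0.26 in NCI-H441, a difference of 2.93 ± 0.25 log2 (adjusted p = 0.0102). The adhesion molecule NECTIN1 differed by 2.80 ± 0.29, the AP-1 factor FOSL1 by 2.86 ± 0.30, CAMK2N1, an inhibitor of CaM kinase II, by 2.13 ± 0.24 and DHRS9 by 3.42 ± 0.40. Differences in the other direction were −3.11 ± 0.31 for MMP13, −2.32 ± 0.28 for TMEM125, −2.29 ± 0.28 for the epithelial transcription factor GRHL1, −4.09 ± 0.52 for SFTPB and −3.41 ± 0.44 for C16orf89, with adjusted p up to 0.0258. The proteasome list differed with camera adjusted p = 8.9e-07 (median 0.51 log2 higher in NCI-H2087), the interferon list with 5.89e-06 (−0.78), the ribosomal list with 1.74e-05 (0.28), the alveolar list with 0.000497 (−1.72), and the mitosis, nucleotide synthesis and hypoxia lists with 0.0115, 0.0127 and 0.0495. These calls were lost with an estimated correlation (adjusted p from 0.71 to 0.864 with an estimated correlation, over the 7 lists called). With the replicate block 1611 genes differed, all 74 among them; interferon genes with a negative difference went from 2 to 16 and alveolar markers from 1 to 9, and 8 mitosis and 6 proteasome genes had a positive one. The count was 0 without either control library of either line, with 7, 9 and 10 genes without NCI-H2087 p53 siRNA replicate 2 and NCI-H441 p53 siRNA replicates 1 and 2, and none of the genes named here kept its call without each library (highest adjusted p from 0.111 to 0.17).

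Fold changes of the 2 replicated lines were related across genes, which are not independent replicates: over 9330 genes r was 0.298 and Spearman's rho 0.274. Of the genes called in NCI-H2087, with 1 left out to give 1559, 68.1% had the same sign in NCI-H441 and 67% in NCI-H2110, against 58.4% and 54.6% of the 9330 genes. Between NCI-H441 and NCI-H2110 r was −0.022 and rho −0.119. The calls of both lines use the same estimate of the spread of each gene. The Fisher tests given here, with or without the block, therefore do not compare independent calls. Without the block the replicated lines shared 1 call (Fisher exact p = 0.0369). That is the only gene called in NCI-H441, so this p shows nothing about a wider shared response. The same gene is among the 13 lower genes shared with the block. With the replicate block 38 higher genes were shared against 6.26 expected from independent calls (p = 5.94e-25, Fisher exact test), and 13 lower genes against 3.29 (p = 4.24e-06), among them CDH1, ANXA2, EFHD2, KRT7, LOXL2 and TNFAIP3 on the higher side and CMTM6, CCDC43, EFCAB14 and ST3GAL5 on the lower.

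In NCI-H2110, compared here without a test, 185 of 12385 genes differed at least 2-fold, 112 higher and 73 lower. Replicates of 1 group in the other lines differed at least 2-fold at 189, 594, 306 and 537 genes. Among the larger differences were IL1A, an inflammatory cytokine (68 and 260 counts), the integrin ITGB8 (123 and 465), ENKUR (14 and 54), the pseudogene SMG1P2 (17 and 118) and the cytochrome P450 gene CYP1A1 (413 and 52). CARNMT1 had 457 and 1341 counts. Several of the largest differences were at read-through loci, which share sequence with their parent genes: PRR5-ARHGAP8 (12 and 55), PEDS1-UBE2V1 (345 and 51), BLOC1S5-TXNDC5 (315 and 0) and DNAAF4-CCPG1 (91 and 0). Summed with their parents, all 8 such loci at least 2-fold apart changed by under 1.5-fold (−0.3454 to 0.4629 log2). For BLOC1S5-TXNDC5 the sums were 20521 and 17507 counts, most of them from the parents. These loci are therefore not read here as genes lost or gained with p53 siRNA.

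Basal and squamous markers had the highest list median in NCI-H2110, 0.65 log2 over 8 members, above all 10000 random lists (percentile 100). The p53-activated targets had a median of 0.12 (percentile 98.55). On the other side were mitosis (−0.12, percentile 2.32), nucleotide synthesis (−0.14, percentile 2.45) and proteasome genes (−0.12, percentile 2.57). Alveolar type 2 markers (−0.56), histone genes (−0.46) and ribosomal protein genes (−0.33) were below all random lists, and NRF2 targets (−0.25) and epithelial genes (−0.24) were at percentile 0.04. Random lists do not keep the correlation between members, and each arm has 1 library. These percentiles are therefore not a test of the siRNA. The share of counts on nuclear pseudogenes of mitochondrial genes was 10.8% and 10.95% in this line.

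The lines differed in marker levels with control siRNA. Summed alveolar type 2 markers were at 1372 CPM in NCI-H2087, 2385 CPM in NCI-H441 and 268 CPM in NCI-H2110, while club and goblet markers were at 174, 153 and 2604 CPM. Immune or endothelial markers summed to 128, 59.5 and 25.4 CPM and fibroblast markers to 15.6, 61.4 and 39.1 CPM. With p53 siRNA the immune or endothelial sum was 312 CPM in NCI-H2087, where CD68 alone was called.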

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

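The tests of the spread between replicates and of the sites in single lines after regression on base composition were chosen only after the result was seen. The regression itself and the comparisons by region and number of sites followed the first result of the sequence search. The splits were set up once the 71 calls were known. The change with p53 siRNA differed between NCI-H2087 and NCI-H441 at 74 genes by a test of the difference itself. Among the named genes the log2 difference was 2.93 for PHLDA1, 2.80 for NECTIN1, 2.86 for FOSL1, 2.13 for CAMK2N1 and 3.42 for DHRS9, and −3.11 for MMP13, −2.32 for TMEM125, −2.29 for GRHL1, −4.09 for SFTPB and −3.41 for C16orf89.

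More genes were called in NCI-H2087 (1560) than in NCI-H441 (1). Both counts come from 1 fit with the same estimate of the spread of each gene, so unequal spreads could not enter as such. Fits of each line alone, with their own spreads, gave 1573 and 0 genes. There a wider spread between the NCI-H441 replicates is argued against for these libraries: their typical difference was 1.12 times that of NCI-H2087. The SD of the fold changes was 0.273 against 0.548. The 95% interval of the ratio, 1.09 to 1.15, was taken over resampled genes. It does not cover how the ratio would vary between libraries, since each arm has 1 pair of replicates. A difference in how well the siRNA worked stays open, as do the line and its p53 mutation as an untested biological explanation.

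For genes higher across the 3 lines, sites for the control siRNA in other transcripts may explain part of the rise, since genes with such a site would be lowered in the control arm alone. The sequence GAATATA, chosen in NCI-H2087, had an effect of 0.0249 log2 in NCI-H441 (permutation p = 0.0047, rank 4708 of 15704 sequences) and 0.1677 in NCI-H2110 (rank 1); after regression on base composition these were 0.0932 and 0.0967, both rank 1. Base composition as the whole cause is argued against by these, and by the 113.3% of the effect across the lines that was left; in NCI-H2110 57.7% was left, so it stays open as a part there. Loss of mutant p53 with no part played by 3′ UTR sites cannot be told apart: genes with GAATATA only in the coding sequence rose by 0.0327 ± 0.0122 across the lines, against 0.1158 ± 0.0103 with 1 site in the 3′ UTR, but this includes the line of the choice, and the others differ (−0.0047 ± 0.0151 against 0.0889 ± 0.0121 in NCI-H441, 0.0932 ± 0.012 against 0.094 ± 0.0092 in NCI-H2110). Genes with more sites rose more, which speaks against it: 0.1914 ± 0.0199 across the lines, 0.1074 ± 0.0233 in NCI-H441, where this is within the spread, and 0.1387 ± 0.0204 in NCI-H2110. A cellular microRNA with the same target sequence was not tested.

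For the count of 71 genes called across the lines, 2 of 100 splits of all libraries, drawn from 126, gave as many, the real one included. The highest other gave 111 and parted 3 of the 5 replicate pairs. The share is under 5%, but splits that keep a correlated pair together are not like the real one, which parts all 5. The 14 splits that part all 5 are too few for a share under 5%, with 71 for the real one and 3 for the highest other. Chance therefore cannot be excluded by these splits.

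For genes lower across the 3 lines, sites for the p53 siRNA could be a source, with CACCCTT in 4 of 8 searched genes. The planned test gave an effect of 0.0209 log2 in NCI-H441 (permutation p = 0.96), which is not the fall that such sites need. After regression on base composition the effect there was −0.0331 (permutation p = 0.0013), so the trend with composition in that line hid what the planned test measured. After this regression, genes with 2 or more sites fell more than those with 1. The values were −0.0786 ± 0.0351 against −0.0204 ± 0.0118 in NCI-H441, and −0.1097 ± 0.0201 against −0.0137 ± 0.0099 in NCI-H2110. Genes with CACCCTT only in the coding sequence did not fall there (0.0512 ± 0.0128 and 0.0351 ± 0.0117). Sites for the p53 siRNA still cannot be told apart from other explanations. Base composition as the whole cause is argued against, with 126.3% of the effect across the lines left after the same regression and −0.0305 in NCI-H2110 (permutation p = 0.0005), but there 37.2% was left, so it stays open as a part. The loss of mutant p53 stays open as an untested biological explanation for these genes.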

How the results depend on the processing

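Leaving out the genes with GAATATA or CACCCTT was chosen after seeing the data and gave 33 genes across the 3 lines, fewer by construction. With no filter on low counts the calls were 2700 in NCI-H2087, 69 in NCI-H441, 1123 across the lines and 810 for the difference between lines; the cause was not tested here or below, unless stated. DESeq2 gave 25 genes in NCI-H441, 609 across the lines, 459 for the difference and 19 shared between NCI-H2087 and NCI-H441, and limma-voom gave 31 for the difference. The replicate block gave 4570 in NCI-H2087, 75 in NCI-H441, 1611 for the difference and 51 shared. Fits of each line alone gave 0 in NCI-H441 (edgeR; 796 at an unadjusted p below 0.05 with all lines) and 0 shared. The mean of the 3 line contrasts gave 214 across the lines. Leaving out 1 library at a time gave 177 (without NCI-H2087 control replicate 2) to 1810 genes in NCI-H2087, 0 to 2 in NCI-H441, 2 to 117 across the lines and 0 to 92 for the difference, with fewer samples in each fit. In NCI-H2110 a minimum of 10 counts gave 637 genes and 200 counts 79, by the number of genes compared, and a fit pooling the spread of all groups gave 1, ENSG00000267645 with 0 and 286 counts, named after its values were seen. Of 72 list tests 16 were called by camera, 0 with an estimated correlation and 2 by fry.

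The other settings left the counts within 1.5 times: in NCI-H2087 RLE factors gave 1567, library totals 1923, DESeq2 2133 and limma-voom 1611, and across the lines RLE factors gave 73, limma-voom 94 and only the replicated lines 61. For named genes called in the main or the other setting, 0 values changed sign. Sign changes of genes called in neither setting were not counted in the replicated lines. Scaling by library totals was left out of these settings, except in NCI-H2110. In NCI-H2087 113 of 1742 values lost a call and 97 gained one, across the lines 114 and 68, and for the difference 97 and 111. Alternatives for normalized units were not run, since the table holds counts. On simulated data at this depth 42.8% of 2-fold changes in a single line were called, which limits what a missing call shows.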
